A study of Caenorhabditis elegans with 15 samples.

How the data were processed

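The series holds 15 libraries in 9 groups from C. elegans strains that express a tagged spliced leader RNA. Per the labels the SL1 and SL2 leaders each carry a base change as the tag. RNA carrying the tag was pulled down with a biotin probe against the tag, reverse transcribed, amplified in 2 rounds of PCR, cut by Tn5 transposase and sequenced in pairs on an Illumina instrument. The submitters' processing notes name Trimmomatic, TopHat2 and DESeq, whose roles and versions are not given in the sources used here, nor is the genome build.

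The deposited table of gene counts holds whole read counts for 14831 genes. In 99.9946% of gene and library pairs the count equals the sum of the reads at that gene's trans-splice acceptor sites in the deposited table of site counts (12 pairs differ), so reads at cis-splice sites are not part of it. The deposited table of RPM values holds these counts divided by 1 number per library, and what that number counts is not stated. The deposited table of sites holds counts at 69542 splice acceptor sites, which the authors annotated as trans sites (19102), cis sites (32276), antisense, intergenic or undetermined, and 90.6% of the cis sites lie at exon starts of the WBcel235 annotation. Further deposited tables give, per gene, the authors' fold change as a ratio of normalised group means, the authors' adjusted p-value, and other columns with the authors' call, whose thresholds are not stated. Other deposited columns give membership of earlier gene sets and the tissue of marker genes chosen by the authors. In each of the tables of counts, RPM values and sites 3 per-sample columns match no library of the series and were not used here.

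Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited gene counts of the 14 SL1-tag libraries, in 1 fit of 8 group means, where L1 and L2 are groups of 1 library each and larval muscle is their mean. Genes were kept by edgeR's filterByExpr with the groups, which left 8954, and libraries were scaled by TMM. The quasi-likelihood F test had 6 residual degrees of freedom (prior degrees of freedom 4.17, common biological coefficient of variation 1.09). Adjusted p-values are edgeR's unless another tool is named, by Benjamini and Hochberg's method over all tested genes, with a threshold of 0.05. SE is the absolute log2 fold change divided by the square root of F. The fitted log2 fold change of a gene without reads in 1 group depends on edgeR's prior count, so such genes are given with a bound.

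Gene lists, 27 in all, were tested with limma's camera (limma 3.58.1) on edgeR's fit with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, where at least 5 members were tested, which made 286 tests. The list of pharyngeal muscle and gland had fewer than 5 tested members and was not tested. Lists that passed in no comparison by camera were cuticle collagens (19 tested genes, smallest adjusted p = 0.061), sperm (5; 0.18), basement membrane (13; 0.0521), glia and coelomocytes (5; 0.164), antioxidant and detoxification (19; 0.185) and autophagy and lysosome (41; 0.108). By fry, which tests a list alone, not against other genes, 4 of these passed: autophagy and lysosome in 8 comparisons (smallest adjusted p = 0.00251), sperm in 4 (0.0101), antioxidant and detoxification in 3 (0.034) and basement membrane in 1 (0.0226). It called 132 lists and camera 105, 91 of them shared. The authors' sets from earlier studies were tested by a one-sided Fisher's exact test over the 8954 tested genes and by camera. Use of trans-splice sites was tested with edgeR's diffSpliceDGE on sites with at least 10 reads in 2 of 4 libraries. The L1, L2 and SL2-tag libraries alone were compared as ratios, for genes with at least 50 reads.

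Genes are named by a rule: promoter genes, the 8 largest changes up and down among called genes whose libraries do not overlap, with a mean log2 CPM of at least 5 in the higher group and a symbol, up to 4 members with the smallest p from each list that passed or belongs to a compared cell type, and the most changed members where a list went both ways. For sites the 5 genes with the smallest p are named. The groups, comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Alternatives were DESeq2's size factors and Wald test (DESeq2 1.42.0), no filter on low counts, a filter of 50 counts in 2 libraries, a block for replicate number, only the groups compared, the SL2-tag library as a further group, L1 and L2 as 1 group, limma on log2(RPM + 1) for 8455 genes with an RPM of at least 1 in 2 libraries, and leaving out each library in turn. With 1 library left in a group, that library is assumed to vary like the other groups. Chosen after seeing the data were limma voom with library weights, counts over trans and cis sites, leaving out the doubted libraries (dauer replicate 2 and both day 12 muscle libraries) and thinning muscle libraries to the neuron depths, with its prediction written before its result was seen. Tables were handled in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.

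The tests were tried on simulated data. For young adult muscle against multiple tissues edgeR recovered 45 of 100 genes changed 64-fold and 6 of 100 changed 8-fold (3.8% false calls), and DESeq2 71 and 25 (48.4%). For neuron age edgeR recovered 39 and 2 of 100 (6.8% false), and for muscle age 57 and 12 (9.2% false). These rates may not hold here, as groups differ in spread. Simulated site use recovered 35 of 40 genes changed 32-fold, with 3 false calls among 161 genes.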

Results

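The libraries measured which RNAs of Caenorhabditis elegans carried a sequence tag that was added to their 5' ends by trans-splicing, the joining of a short spliced leader RNA to a pre-mRNA. A tagged SL1 spliced leader was expressed from the U2-3 promoter in multiple tissues of a mixed-stage culture (2 libraries), from the myo-3 promoter in body-wall muscle, and from the rgef-1 promoter in neurons. Muscle was sampled at L1 (1 library), L2 (1 library), dauer, the arrested larval stage (2 libraries), young adult (2 libraries) and day 12 of adulthood (2 libraries). Neurons were sampled in young adults and on day 12, with 2 libraries each. A further muscle library (1, mixed stage) carried a tagged SL2 leader, the leader that is mostly joined to downstream genes of operons. Its title and strain label name SL2 and its description SL1, and it is taken as SL2 here because 97.7% of its reads lie in operon genes. Worms were kept at 20 °C, and day 12 animals had received 400 µM fluorodeoxyuridine, which blocks the production of progeny.

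Reads assigned to genes ranged from 57104 in day 12 neuron replicate 1 to 9587967 in dauer muscle replicate 2. The other libraries held 2196322 and 3636542 (multiple tissues), 709137 (L1), 1815663 (L2), 1974529 (dauer replicate 1), 992136 and 2289349 (young adult muscle). Further totals were 464359 and 1684401 (day 12 muscle), 253647 and 282171 (young adult neurons), 112074 (day 12 neuron replicate 2) and 2520944 (SL2 tag). At least 1 read fell on 7650 and 8056 genes in the multiple-tissue libraries, and on 7945 and 4569 genes in the 2 dauer libraries. The biological coefficient of variation within a group was 0.058 for multiple tissues, 0.393 for young adult muscle, 1.39 for dauer muscle. It was 1.35 for day 12 muscle, 0.571 for young adult neurons and 0.411 for day 12 neurons. Across genes, Spearman's rho between the replicates was 0.986 for multiple tissues, 0.889 for young adult muscle, 0.701 for dauer, 0.469 for day 12 muscle, 0.695 for young adult and 0.6 for day 12 neurons, where genes are not independent replicates. Levels are CPM, counts scaled by edgeR to a common library size, with the SD over 2 libraries per group, and fold changes are on the log2 scale with their standard error (SE). Where 2 adjusted p-values follow camera, the first is with the preset and the second with an estimated correlation. A fold against a group in which no library held a read is given as a bound, computed from 3 counts over that group. A second value after it is the lowest bound with any 1 library left out, always replicate 2 (L2 for larvae) of the group without reads. Such bounds cover counting error only, because PCR reads without molecular identifiers are not independent molecules. edgeR's p-values use 1 spread per gene, pooled over all groups of labelled biological replicates.

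**Figure D1:**
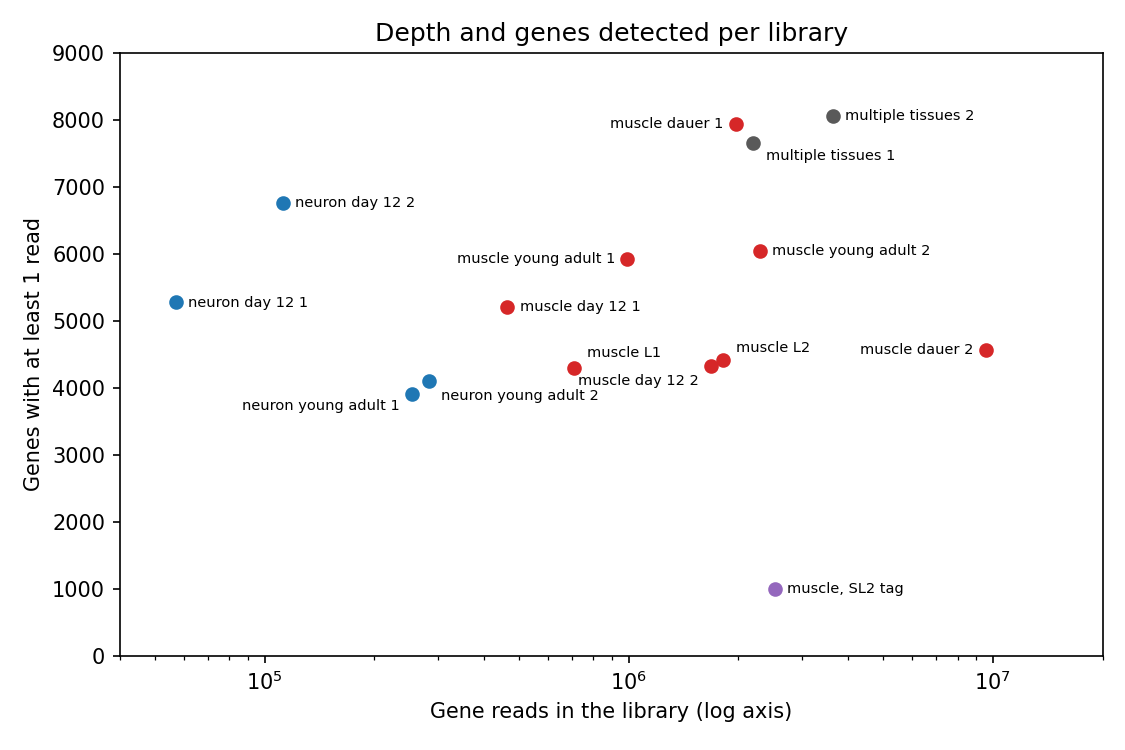
Each point is 1 library, with its gene reads on a log axis and the number of genes with at least 1 read on the vertical axis, for multiple tissues (grey), muscle (red), neurons (blue) and the SL2-tag library (purple).

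Transcripts of myo-3 (WBGene00003515), the muscle myosin heavy chain gene whose promoter drove the tag in muscle, were read 117 and 133 times in young adult muscle, 58 times in L1, 543 times in L2, 30 and 1714 times in dauer, 0 and 35 times in day 12 muscle, and 0 and 1 times in multiple tissues. It had no neuron reads (3 counts: 52.5 unscaled CPM in the shallowest library). Its log2 fold change over multiple tissues did not pass the threshold of 0.05 in young adult muscle (8.63 ± 2.42 SE, edgeR adjusted p = 0.0903), day 12 muscle (5.30 ± 2.19; 0.157), dauer (8.23 ± 2.38; 0.079) or larvae (9.25 ± 2.47; 0.062). Without day 12 muscle replicate 2 the day 12 value was -2.11, since replicate 1 held no read of it. For rgef-1, the neuronal Ras exchange factor gene, the table of gene counts has no entry, and 5, 1 and 2 reads fell on its cis-splice sites in young adult neuron replicate 2 and the day 12 neuron libraries.

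The comparison of young adult muscle with multiple tissues asks which transcripts the muscle-driven tag captured beyond the broadly driven one. The multiple-tissue libraries are of mixed stage, so that tissue and stage differ together in each comparison against them. Genes of the contractile apparatus were higher in muscle. Transcripts of unc-87 (WBGene00006819), a thin filament protein, stood at 8852 ± 0.064 CPM against 8.1 ± 0.661, a log2 fold change of 10.08 ± 0.68 (SE, adjusted p = 9.95e-05), n = 2 per group. The troponin genes tni-3 (11.78 ± 1.09, adjusted p = 0.000528), tnt-2 (9.56 ± 0.87; 0.000528) and unc-27 (8.71 ± 0.72; 0.000183) and the myosin light chain gene mlc-2 (9.22 ± 0.78; 0.00035) rose as well. Of 22 tested sarcomere filament genes 12 were higher and 0 lower, or 16 and 0 adjusted over the list alone (camera adjusted p = 6.13e-11, or 0.0354 with an estimated correlation). Among 24 genes of the dense bodies and M-lines, which anchor the filaments to the cell membrane, 10 were higher and 0 lower (18 and 0 over the list alone, camera adjusted p = 6.13e-11, or 0.00671). They include the profilin gene pfn-3 (9.82 ± 0.90), the LIM protein genes lim-9 (8.38 ± 0.99) and unc-95 (10.55 ± 1.27), dim-1 (8.69 ± 1.04) and the paxillin gene pxl-1 (at least 305-fold, or 117, higher, 215 ± 33.1 CPM against 0).

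Of 21 genes for muscle excitation and calcium handling 5 were higher and 0 lower (14 and 0 over the list alone, camera adjusted p = 3.61e-08, or 0.064 with an estimated correlation). The calsequestrin gene csq-1 had the smallest p (7.55 ± 1.02, adjusted p = 0.00344), next to the dystrobrevin gene dyb-1 (7.42 ± 1.42). The muscle regulator unc-120, an SRF-type transcription factor, rose by 8.92 ± 1.39 (adjusted p = 0.00656), although its list of 6 transcription factors, with 2 higher, did not pass (camera adjusted p = 0.0626). Of 36 pan-neuronal genes 3 were higher in muscle, the syntaxin gene unc-64 (6.24 ± 1.07), rab-3 (5.35 ± 1.14) and the synaptobrevin gene snb-1 (3.00 ± 0.74), and 0 lower (camera adjusted p = 0.0184, or 0.298). The glyceraldehyde phosphate dehydrogenase genes split by paralog. Both members in an operon, gpd-3 (6.90 ± 0.68) and gpd-2 (4.69 ± 0.69), were higher, and gpd-1 was at least 1881-fold (or 599.8) lower. With them, 3 of 8 operon downstream genes were higher (camera adjusted p = 0.0435, or 0.384).

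Germline transcripts were lower in young adult muscle than in multiple tissues. Of 45 germline and oocyte genes 8 were lower and 0 higher, or 26 and 0 adjusted over the list alone (camera adjusted p = 1.3e-12, or 0.0459 with an estimated correlation). Reads of egg-1, needed on the egg surface for fertilisation, stood at 1434 CPM in multiple tissues and 0 in muscle, at least 1166-fold (or 372) lower. The oocyte RNA-binding protein genes puf-5 (at least 1126-fold, or 359) and daz-1 (at least 512-fold, or 163) were lower too. Of 44 replication and cell cycle genes 7 were lower and 1 higher (18 and 1 over the list alone, camera adjusted p = 6.13e-11, or 0.172). The lower ones include the cyclin B gene cyb-2.2 (at least 1241-fold, or 396) and the ribonucleotide reductase gene rnr-2 (-5.36 ± 0.99). The linker histone gene hil-1 was higher (3.83 ± 0.95). The intestinal gene asp-1 was at least 295-fold (or 94.1) lower, the 1 called of 18 intestine genes (camera adjusted p = 0.0057, or 0.367).

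In all, 458 of 8954 tested genes differed in young adult muscle (352 higher, 106 lower; edgeR), and in all 458 the libraries of the 2 groups did not overlap, which chance gives in 33.3% of genes. The count fell to 204 and 188 without multiple-tissue replicate 1 or 2, and to 180 and 175 without young adult muscle replicate 1 or 2. DESeq2's Wald test gave 1201. Over the alternatives 33.5% (limma on log2(RPM + 1)) to 94.4% (without young adult muscle replicate 1) of calls were higher. Of 42 called genes looked at singly, 15 kept their call without any 1 of these 4 libraries. The ranges in brackets are the fitted log2 fold changes over the leave-outs, which depend on edgeR's prior count, here and for other comparisons, where a gene had no read in a group. gpd-1 (-15.06 to -14.96), cyb-2.2 (-14.46 to -14.38), egg-1 (-14.37 to -14.28), puf-5 (-14.36 to -14.18), asp-1 (-12.39 to -12.29) and daz-1 (-13.25 to -13.02) missed 0.05 without young adult muscle replicate 1 or 2. dyb-1 (6.37 to 9.61) lost the call without multiple-tissue replicate 1 or 2 or young adult muscle replicate 1. unc-64 (5.96 to 6.49) did not pass without multiple-tissue replicate 1 or 2 or young adult muscle replicate 2. rab-3 (4.43 to 9.29) missed 0.05 without multiple-tissue replicate 1 or young adult muscle replicate 1 or 2. snb-1 (2.82 to 3.12) and hil-1 (3.22 to 4.24) lost the call without each of the 4 libraries in turn. rnr-2 (-6.83 to -4.67) did not pass without young adult muscle replicate 1. gpd-2 (4.58 to 4.74) missed 0.05 without multiple-tissue replicate 2.

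**Figure D2:**
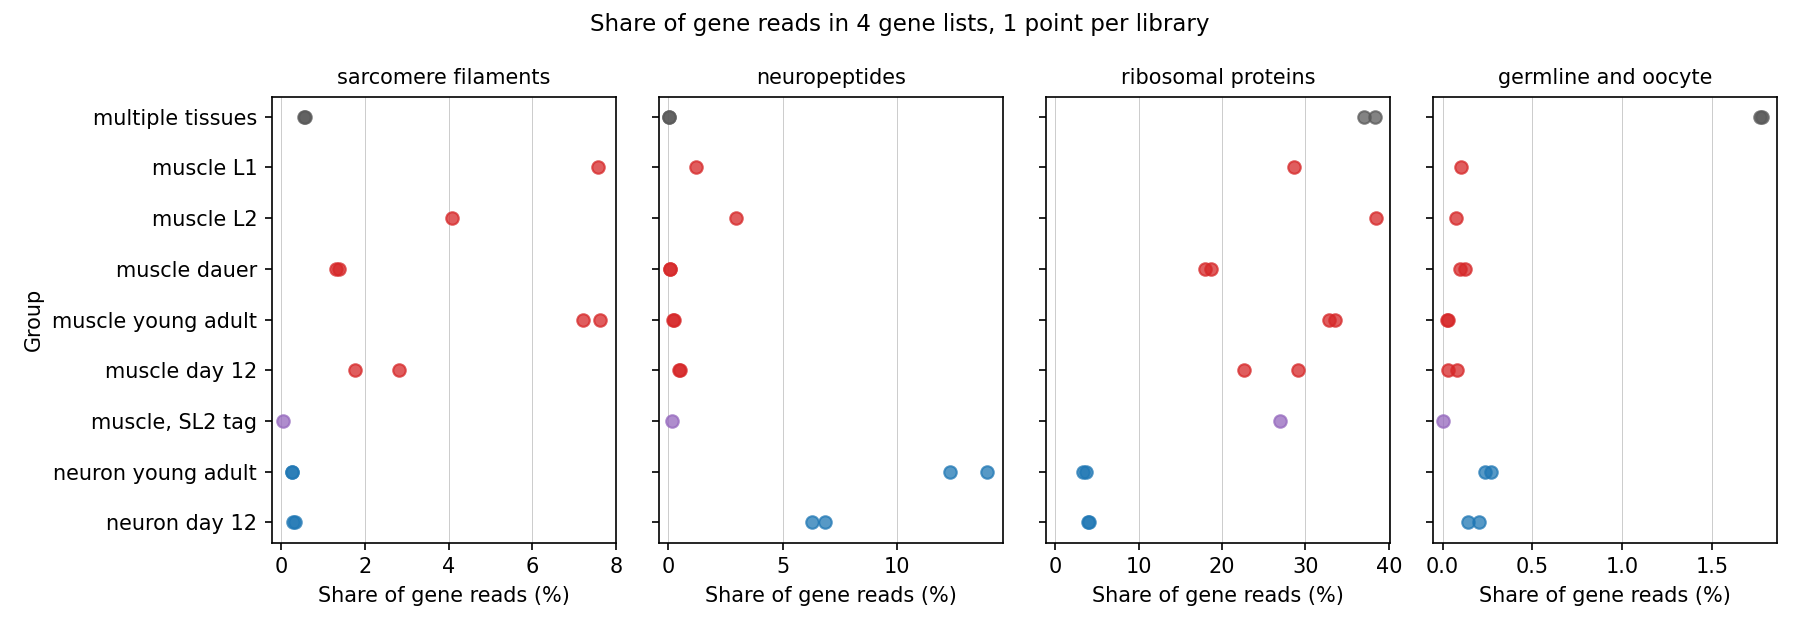
Share of gene reads in 4 gene lists, with 1 point per library, for multiple tissues (grey), muscle (red), the SL2-tag library (purple) and neurons (blue). Sarcomere genes hold 7.63% and 7.21% of reads in young adult muscle and 0.556% and 0.531% in multiple tissues.

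Muscle of day 12 adults was set against multiple tissues in the same way, to ask which transcripts the tag captured in old muscle. Sarcomere genes were higher: unc-87 stood at 4724 ± 792 CPM against 8.1 ± 0.661, a log2 fold change of 9.18 ± 0.66 (SE, adjusted p = 0.000137), n = 2 per group. Of 22 sarcomere filament genes 10 were higher, among them mlc-2 (7.86 ± 0.74), tni-3 (10.17 ± 1.05) and unc-27 (5.46 ± 0.63), and 1 was lower, the actin gene act-2 (-4.52 ± 0.98). Adjusted over the list alone these counts were 12 and 2 (camera adjusted p = 8.84e-06, or 0.114 with an estimated correlation). Of 24 attachment genes 8 were higher and 0 lower (9 and 0 over the list alone, camera adjusted p = 1.91e-06, or 0.0173), with pfn-3 at 9.29 ± 0.88 and pat-6, the parvin gene, at 5.29 ± 0.69. Excitation and calcium genes were higher in 5 of 21 cases (7 over the list alone, camera adjusted p = 4.87e-05, or 0.148), with csq-1 at 5.57 ± 0.94. Neuropeptide genes were higher in 9 of 50 cases and lower in 0 (17 and 2 over the list alone, camera adjusted p = 1.42e-05, or 0.148), led by nlp-20 at 2035 ± 851 CPM against 56.6 ± 1.37 (5.17 ± 0.35).

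Genes of protein synthesis and turnover were lower in day 12 muscle than in multiple tissues. Of 78 ribosomal protein genes 38 were lower and 0 higher (47 and 1 over the list alone, camera adjusted p = 1.89e-09, or 0.327 with an estimated correlation), such as rpl-16 (-3.12 ± 0.27) and rpl-5 (-3.50 ± 0.39). Proteasome genes were lower in 13 of 32 cases and higher in 0 (26 and 0 over the list alone, camera adjusted p = 2.85e-07, or 0.0173), with the lid gene rpn-5 at -5.14 ± 0.79. Of 29 chaperone genes 9 were lower, including the Hsp90 gene daf-21 (-4.01 ± 0.58) and the chaperonin gene cct-1 (-7.32 ± 1.26), and 2 were higher, including the small heat shock gene hsp-25 (4.75 ± 0.71). The list's counts were 16 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.000683, or 0.114). Citrate cycle genes were lower in 5 of 26 cases, with dlst-1, of the oxoglutarate dehydrogenase complex, at -9.06 ± 1.09 (13 lower and 1 higher over the list alone, camera adjusted p = 0.00715, or 0.327). Germline genes were lower in 13 of 45 cases (camera adjusted p = 6.89e-10, or 0.114), with puf-5 at least 1049-fold (or 311) lower. Cell cycle genes were lower in 8 of 44 cases and higher in 1 (camera adjusted p = 1.1e-06, or 0.24), with cyb-2.2 at least 1156-fold (or 342) lower.

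edgeR called 879 genes in day 12 muscle (437 higher, 442 lower), of which 876 had libraries that did not overlap (33.3% by chance in unselected genes). The split depends on scaling: with DESeq2's size factors the median log2 fold change of all genes moved from -0.29 to 0. Over the alternatives 26.6% (limma on log2(RPM + 1)) to 70.5% (DESeq2's size factors) of calls were higher. Without multiple-tissue replicate 1 or 2 the count was 307 or 239, without day 12 replicate 1 or 2 it was 899 or 694, and 34 of 54 called genes looked at singly kept their call throughout. csq-1 (5.08 to 5.80) missed 0.05 without multiple-tissue replicate 1 or 2. act-2 (-4.65 to -4.53) lost the call without day 12 muscle replicate 1 or 2.

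Muscle on day 12 was then compared with muscle of young adults. Only day 12 animals had received fluorodeoxyuridine, so that age and drug differ together here, in neurons and in the interaction, and drug also differs between day 12 and multiple-tissue libraries. Contractile genes were lower in old muscle: the actin gene act-1 (WBGene00000063) went from 44390 ± 328 CPM in young adults to 1402 ± 1177, a log2 fold change of -4.98 ± 0.58 (SE, adjusted p = 0.00637), n = 2 per group. The troponin genes tnt-2 (-5.07 ± 0.71) and unc-27 (-3.25 ± 0.56) fell as well, making 3 of 22 sarcomere genes lower and 0 higher, or 6 and 0 adjusted over the list alone (camera adjusted p = 1.34e-05, or 0.049 with an estimated correlation). Of 24 attachment genes 0 passed singly in edgeR and 1 was lower adjusted over the list alone, with lim-9 at -3.13 ± 0.76 (adjusted p = 0.0719 over all genes), while the list as a whole lay lower (camera adjusted p = 0.000491, or 0.0471). Proteasome genes were lower in 2 of 32 cases, pas-2 (-3.35 ± 0.69) and pas-5 (-2.38 ± 0.50), and in 20 adjusted over the list alone, with 0 higher (camera adjusted p = 5.13e-11, or 0.00548). Chaperone genes were lower in 4 of 29 cases, the chaperonin genes cct-5 (-4.08 ± 0.54), cct-1 (-7.60 ± 1.27) and cct-4 (-5.99 ± 1.24) and the Hsp90 gene daf-21 (-3.29 ± 0.56); adjusted over the list alone 14 were lower and 1 higher (camera adjusted p = 1.27e-06, or 0.0471).

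Ribosomal protein genes were lower in 14 of 78 cases in old muscle and higher in 0 (35 and 0 over the list alone, camera adjusted p = 7.43e-12, or 0.331 with an estimated correlation), such as rpl-3 (-3.39 ± 0.37) and rpl-16 (-2.14 ± 0.26). Of 26 citrate cycle genes 2 were lower, dlst-1 (-10.04 ± 1.12) and the citrate synthase gene cts-1 (-4.13 ± 0.76) (4 over the list alone, camera adjusted p = 0.0015, or 0.331). Of 26 genes of glycolysis and gluconeogenesis the enolase gene enol-1 was lower (-3.33 ± 0.67); 8 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0213, or 0.353). Of 50 neuropeptide genes 4 were higher and 0 lower, or 20 and 0 adjusted over the list alone (camera adjusted p = 5.9e-10, or 0.061), with flp-24 at least 107-fold (or 34.2), flp-26 at least 51-fold (or 16.2) and flp-28 at least 17-fold (or 5.43) higher and 0 CPM in young adult muscle. In the insulin and dauer list 2 of 30 genes were higher, the long noncoding RNA tts-1 (3.93 ± 0.47) and the insulin-like gene ins-10 (at least 27.5-fold, or 8.78) (5 higher and 1 lower over the list alone, camera adjusted p = 0.00761, or 0.0709). Innate immunity genes passed as a list (camera adjusted p = 0.000272, or 0.233) with 0 of 18 past the threshold over all genes and 4 adjusted over the list alone, where the saposin-like gene spp-9 had 0.057 and the lysozyme gene lys-7 0.0719 as adjusted p over all genes in edgeR. Day 12 replicate 1 carried most of this rise, with 0.572% of reads in the list against 0.053% in replicate 2 and 0.002% and 0.008% in young adults. It also held more reads of intestine genes (0.19% against 0.015% in replicate 2), of which asp-1 rose (at least 33-fold, or 10.5), and none of myo-3.

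Of all genes 139 differed with age in muscle (54 higher, 85 lower, edgeR), all 139 with libraries that did not overlap (33.3% by chance in unselected genes). With DESeq2's size factors 74 of 108 calls were higher, 68.5% in place of 38.8%, and with limma on log2(RPM + 1) 34.1%. A fit of only the groups compared called 0 of 4782 genes (edgeR, 1491 at an unadjusted p under 0.05, smallest adjusted p = 0.0721). No gene was called by edgeR without young adult muscle replicate 1 or without replicate 2 (0 and 0). The whole comparison has 1724 genes at an unadjusted p of 0.05, and DESeq2's Wald test called 882 and limma on log2(RPM + 1) 881. The count was 227 without day 12 replicate 2 and 167 without replicate 1. None of 35 called genes looked at singly kept its call in all 4 cases. flp-24 (10.70 to 10.98), flp-26 (9.71 to 9.85), act-1 (-6.29 to -4.32), tnt-2 (-5.27 to -4.92), flp-28 (7.36 to 8.74), rpl-3 (-3.62 to -3.22), rpl-16 (-2.28 to -2.03), enol-1 (-4.68 to -2.67), dlst-1 (-13.66 to -9.49), cct-5 (-4.54 to -3.75), cct-4 (-12.28 to -5.17) and tts-1 (3.39 to 4.30) missed 0.05 without young adult muscle replicate 1 or 2. asp-1 (8.06 to 9.74), ins-10 (8.36 to 9.26), unc-27 (-3.39 to -3.10), cts-1 (-5.07 to -3.61), pas-5 (-3.27 to -1.85) and cct-1 (-8.50 to -7.21) lost the call without young adult muscle replicate 1 or 2 or day 12 muscle replicate 1. pas-2 (-3.55 to -3.13) and daf-21 (-3.52 to -3.12) did not pass without each of the 4 libraries in turn.

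Against multiple tissues, dauer muscle had higher transcripts of unc-87 (1964 ± 475 CPM against 8.1 ± 0.661), a log2 fold change of 7.91 ± 0.63 (SE, adjusted p = 0.00014), n = 2 per group, and of tni-3 (10.67 ± 1.06), unc-27 (5.61 ± 0.63) and mlc-2 (5.26 ± 0.66). They belong to the 10 of 22 sarcomere genes that were higher, with 0 lower (13 and 2 over the list alone, camera adjusted p = 7.68e-07, or 0.101 with an estimated correlation). Of 24 attachment genes 8 were higher and 0 lower (16 and 0 over the list alone, camera adjusted p = 3.07e-08, or 0.0164), including pxl-1 (at least 547-fold, or 210.2) and pfn-3 (9.05 ± 0.88). Excitation and calcium genes were higher in 6 of 21 cases (11 over the list alone, camera adjusted p = 4.42e-06, or 0.129), including dyb-1 (7.03 ± 1.41). The regulator unc-120 was higher by 9.21 ± 1.40. Pan-neuronal genes were higher in 3 of 36 cases, unc-64 (5.73 ± 1.05), cpx-1, the complexin gene (3.18 ± 0.63), and rab-3 (4.96 ± 1.12) (camera adjusted p = 0.0137, or 0.234).

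Of 78 ribosomal protein genes 45 were lower in dauer muscle and 0 higher (61 and 1 over the list alone, camera adjusted p = 6.38e-16, or 0.234 with an estimated correlation), such as rpl-16 (-2.52 ± 0.27) and rla-2 (-2.90 ± 0.38). Germline genes were lower in 8 of 45 cases (19 over the list alone, camera adjusted p = 3.06e-11, or 0.101), with egg-1 at least 6092-fold (or 983 without dauer replicate 2) lower. Cell cycle genes were lower in 7 of 44 cases (camera adjusted p = 1.91e-10, or 0.223), such as the PCNA gene pcn-1 (-5.91 ± 1.17), and hil-1 was higher (7.08 ± 1.07). In the proteasome list of 32 rpn-10 was higher (3.53 ± 0.67) and rpn-5 lower (-2.77 ± 0.70). The list lay lower (camera adjusted p = 0.0129, or 0.101). The malate dehydrogenase gene mdh-2 was lower (-3.65 ± 0.75), the 1 called of 26 citrate cycle genes (camera adjusted p = 0.0137, or 0.394). Intestine and innate immunity genes, 18 each, lay lower as lists (camera adjusted p = 0.0199 and 0.0255, adjusted p = 0.458 and 0.456 with an estimated correlation) with 0 single calls by edgeR.

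Dauer muscle had 667 called genes (460 higher, 207 lower, edgeR), with 2108 at an unadjusted p of 0.05. All 667 had libraries that did not overlap (33.3% by chance in unselected genes). Over the alternatives 41% (limma on log2(RPM + 1)) to 83.7% (without dauer replicate 2) of calls were higher. Without multiple-tissue replicate 1 or 2 it had 258 or 229, and without dauer replicate 1 it had 1230 and without replicate 2 478. Of 43 called genes looked at singly 25 kept their call without any 1 library. dyb-1 (5.98 to 9.25), unc-64 (5.18 to 5.96) and rpn-10 (3.37 to 3.59) missed 0.05 without multiple-tissue replicate 1 or 2. cpx-1 (2.55 to 4.00) and rab-3 (3.81 to 8.89) lost the call without multiple-tissue replicate 1 or dauer replicate 2. mdh-2 (-4.05 to -3.49) did not pass without multiple-tissue replicate 1 or 2 or dauer replicate 2. rpn-5 (-3.07 to -2.67) missed 0.05 without each of the 4 libraries in turn. Replicate 2, the library with 4569 genes against 7945, is doubted for that reason, and without it and both day 12 muscle libraries the count was 2205, a setting chosen after seeing the data.

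Larval muscle, the mean of 1 L1 and 1 L2 library, was tested against multiple tissues with the spread of replicated groups. Transcripts of unc-87 (4282 ± 2072 CPM against 8.1 ± 0.661), a log2 fold change of 8.95 ± 0.65 (SE), mlc-2 (8.95 ± 0.77) and the troponin T gene mup-2 (9.62 ± 1.09) were higher. Of 22 sarcomere genes 10 were higher and 2 lower, the lower ones including act-2 (-5.51 ± 1.03), or 14 and 2 adjusted over the list alone (camera adjusted p = 5.75e-12, or 0.0238 with an estimated correlation). Attachment genes were higher in 9 of 24 cases (14 over the list alone, camera adjusted p = 1e-11, or 0.00545), with pfn-3 (8.93 ± 0.87) and lim-9 (7.92 ± 0.97) among them. Excitation and calcium genes were higher in 5 of 21 cases (10 higher and 1 lower over the list alone, camera adjusted p = 6.05e-07, or 0.0778), with csq-1 at 6.39 ± 0.97. Of 6 muscle transcription factors unc-120 was higher (7.71 ± 1.33, camera adjusted p = 0.0131, or 0.111), and of 36 pan-neuronal genes 3 were, including cpx-1 (4.63 ± 0.67) and rab-3 (6.88 ± 1.20) (camera adjusted p = 0.00936, or 0.206). Their median log2 fold change was 0, against -1.43 over all genes.

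Germline genes were lower in 14 of 45 cases in larval muscle and in 35 adjusted over the list alone (camera adjusted p = 8.4e-10, or 0.0411 with an estimated correlation), with pos-1, a maternal zinc finger protein gene, at least 4478-fold (or 1304) lower. Cell cycle genes were lower in 12 of 44 cases (27 over the list alone, camera adjusted p = 8.4e-10, or 0.155), with psf-1 of the replicative helicase at least 454-fold (or 132) lower and rnr-2 at -12.19 ± 1.44. Proteasome genes were lower in 5 of 32 cases (8 over the list alone, camera adjusted p = 0.00083, or 0.0411), such as pbs-4 (-3.14 ± 0.54). The intestinal genes asp-1 (-9.72 ± 1.69) and lys-1 (at least 46.5-fold, or 13.5) were lower, 2 of 18 (camera adjusted p = 0.0243, or 0.538).

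In larval muscle 628 genes were called (316 higher, 312 lower, edgeR), 622 of them with libraries that did not overlap (33.3% by chance in unselected genes). Over the alternatives 23.1% (limma on log2(RPM + 1)) to 78.6% (without L2) of calls were higher. Leaving out a library gave 293 or 258 (multiple-tissue replicate 1 or 2), 388 (L1) or 379 (L2). Of 46 called genes looked at singly 22 kept their call without any 1 library. pos-1 (-16.49 to -16.32) missed 0.05 without L1 or L2. csq-1 (5.47 to 7.24) and pbs-4 (-3.39 to -2.96) lost the call without multiple-tissue replicate 2. rab-3 (5.98 to 10.81) did not pass without multiple-tissue replicate 1. asp-1 (-12.40 to -7.11) and act-2 (-7.18 to -3.91) missed 0.05 without L1. lys-1 (-9.89 to -9.74) lost the call without each of the 4 libraries in turn.

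Dauer muscle was compared with L1 and L2 muscle (1 library each), as the labels of the authors' deposited table imply. Neuropeptide genes differed in both directions. Transcripts of nlp-20 went from 22550 ± 14840 CPM in larvae to 184 ± 19.1 in dauers, a log2 fold change of -6.76 ± 0.38 (SE). Those of flp-24 (-8.50 ± 0.97) were lower too, while flp-10 was at least 88.3-fold (or 25.7) higher. In all 4 of 50 neuropeptide genes were higher and 5 lower, over all genes and adjusted over the list alone, so that the list's call (camera adjusted p = 0.0225, or 0.615 with an estimated correlation) hides a split. Of 22 sarcomere genes 4 were lower, act-1 (-3.42 ± 0.54), mlc-2 (-3.69 ± 0.61), tni-1 (-4.12 ± 0.84) and mup-2, and 0 higher (6 and 1 over the list alone, camera adjusted p = 0.0282, or 0.467). Ribosomal protein genes were lower in 17 of 78 cases and higher in 1 (47 and 1 over the list alone, camera adjusted p = 3.29e-33, or 0.438), such as rps-22 (-2.24 ± 0.34). Of 40 genes of oxidative phosphorylation 2 were lower, the cytochrome c gene cyc-2.1 (-3.62 ± 0.74) and the cytochrome oxidase gene cco-1 (-1.96 ± 0.41), and the ATP synthase gene asb-1 was higher (6.21 ± 1.29) (camera adjusted p = 1.34e-05, or 0.588). In the citrate cycle list of 26 mdh-2 was lower (-3.48 ± 0.74, camera adjusted p = 1.34e-05, or 0.438). The calcium pump gene sca-1 was higher (6.93 ± 1.47), the bZIP transcription factor gene zip-8 at least 456-fold (or 133) higher, and the thymosin beta gene tth-1 at least 176-fold (or 51.4) higher. The stomatin gene sto-2 was at least 738-fold (or 119 without dauer replicate 2) lower. The median log2 fold change of all genes was 1.35.

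Between dauer and larval muscle 295 genes were called (241 higher, 54 lower; edgeR), 289 with libraries that did not overlap (33.3% by chance). L1 and L2 as 1 group gave 93, and a fit of only the groups compared 0 of 6713 (edgeR, 1442 at an unadjusted p under 0.05, smallest adjusted p = 0.133; 1168 by DESeq2's Wald test). Over the alternatives 55.9% (without dauer replicate 1) to 90.4% (without dauer replicate 2) of calls were higher. The count was 136 without L1, 48 without L2, 524 without dauer replicate 1 and 156 without dauer replicate 2. Of 31 called genes looked at singly 7 kept their call without any 1 library, here nlp-20, flp-24, rps-22 and sto-2 (-11.84 to -2.18) and zip-8 and tth-1 (11.15 to 13.17). act-1 (-3.90 to -2.95) missed 0.05 without dauer replicate 2. mlc-2 (-3.98 to -3.43) lost the call without dauer replicate 1 or 2. tni-1 (-4.62 to -3.74), cyc-2.1 (-4.07 to -3.18) and cco-1 (-2.38 to -1.56) did not pass without each of the 4 libraries in turn. mup-2 (-5.12 to -3.40), mdh-2 (-3.97 to -3.01), asb-1 (1.70 to 10.71) and sca-1 (3.48 to 10.36) missed 0.05 without L1 or L2 or dauer replicate 2. flp-10 (10.07 to 10.80) lost the call without L2.

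The rgef-1 promoter drove the tag in neurons, and young adult neurons were compared with multiple tissues. Neuropeptide genes were the most raised group: 34 of 50 were higher and 0 lower, or 40 and 1 adjusted over the list alone (camera adjusted p = 7.07e-20, or 0.0327 with an estimated correlation). Transcripts of nlp-20 (WBGene00003758) stood at 52360 ± 9881 CPM against 56.6 ± 1.37, a log2 fold change of 9.85 ± 0.43 (SE, adjusted p = 3.85e-06), n = 2 per group, those of nlp-10 at 17960 ± 3534 CPM (13.53 ± 1.01), and flp-15 was at least 2176-fold (or 836) higher. Of 36 pan-neuronal genes 5 were higher and 0 lower (4 and 0 over the list alone, camera adjusted p = 0.000242, or 0.11). The complexin gene cpx-1 reached 22780 ± 3507 CPM (11.53 ± 0.88, adjusted p = 5.56e-05), next to rab-3 (8.23 ± 1.27) and the tau-like gene ptl-1 (8.41 ± 1.39). The synaptotagmin gene snt-3 was at least 3347-fold (or 1286) higher. In the insulin and dauer list 7 of 30 genes were higher, including ins-17 (11.19 ± 0.98), and 1 lower (8 and 2 over the list alone, camera adjusted p = 0.0068, or 0.0878). Of 11 genes of sensory cilia 2 were higher, the kinesin gene klp-11 (10.10 ± 2.65) and the TRPV channel gene ocr-2 (at least 38.5-fold, or 14.8) (camera adjusted p = 0.027, or 0.185). Neurotransmitter genes had 0 calls among 9 in edgeR, where 3157 of all genes had an unadjusted p under 0.05 (camera adjusted p = 0.0645). In the list of muscle excitation 4 of 21 genes were higher, including dyb-1 (9.69 ± 1.53) and the calcium-dependent kinase gene unc-43 (6.82 ± 1.49), both also known from neurons, and 1 lower, sca-1 (at least 5.24-fold, or 2.62) (camera adjusted p = 0.00346, or 0.185).

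Ribosomal protein genes were lower in young adult neurons in 74 of 78 cases and higher in 0 (76 and 0 over the list alone, camera adjusted p = 1.96e-28, or 0.123 with an estimated correlation). Transcripts of rpl-16 stood at 791 ± 0.73 CPM against 12960 ± 545 (-4.03 ± 0.29), and rpl-1 at -6.04 ± 0.42. Proteasome genes were lower in 19 of 32 cases (27 over the list alone, camera adjusted p = 9.25e-08, or 0.0158), with pbs-1 at -4.87 ± 0.57. Chaperone genes were lower in 12 of 29 cases and higher in 1 (18 and 1 over the list alone, camera adjusted p = 0.00107, or 0.0878): the Hsp70 gene hsp-1 (-8.16 ± 1.09) and daf-21 (-4.87 ± 0.61) were lower and hsp-25 (5.07 ± 0.73) higher. Genes of oxidative phosphorylation were lower in 16 of 40 cases, such as ucr-1 (-4.06 ± 0.79) (camera adjusted p = 0.00315, or 0.421). Citrate cycle genes were lower in 8 of 26 cases, such as mdh-2 (-4.34 ± 0.80) (camera adjusted p = 0.00387, or 0.274). Germline genes were lower in 18 of 45 cases (camera adjusted p = 5.34e-07, or 0.0878), with egg-1 at least 264-fold (or 132) lower. Cell cycle genes were lower in 14 of 44 cases and higher in 1 (camera adjusted p = 6.02e-06, or 0.222), with rnr-2 at least 408-fold (or 204) lower.

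Young adult neurons had 1523 called genes (698 higher, 825 lower; edgeR), 1514 with libraries that did not overlap (33.3% by chance). With DESeq2's size factors the median of all genes moved from -2.05 to -1.19. Over the alternatives 27.5% (limma on log2(RPM + 1)) to 66.6% (DESeq2's size factors) of calls were higher. Leaving out multiple-tissue replicate 1 or 2 gave 819 or 745 calls and leaving out neuron replicate 1 or 2 gave 849 or 918. Of 61 called genes looked at singly 46 kept their call each time. unc-43 (6.36 to 7.24) missed 0.05 without multiple-tissue replicate 1 or 2. sca-1 (-8.79 to -8.55), klp-11 (9.31 to 12.08) and ocr-2 (8.36 to 8.94) lost the call without each of the 4 libraries in turn.

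Neurons of day 12 adults, compared with multiple tissues, had higher neuropeptide transcripts: nlp-20 at 6484 ± 882 CPM against 56.6 ± 1.37, a log2 fold change of 6.84 ± 0.38 (SE, adjusted p = 4.22e-05), n = 2 per group, nlp-11 at 8.35 ± 0.63 and nlp-10 at 10.35 ± 0.91. Of 50 neuropeptide genes 32 were higher and 0 lower, or 42 and 0 adjusted over the list alone (camera adjusted p = 3.25e-18, or 0.0387 with an estimated correlation). The complexin gene cpx-1 (10.38 ± 0.85), rab-3 (8.53 ± 1.28) and ptl-1 (7.12 ± 1.33) were among 5 of 36 pan-neuronal genes that were higher, with 0 lower (camera adjusted p = 0.000815, or 0.153). Neurotransmitter genes had 0 calls of 9 over all genes in edgeR and 5 higher adjusted over the list alone (camera adjusted p = 0.0491, or 0.369). In the insulin and dauer list 7 of 30 were higher and 1 lower, with ins-15 at least 2168-fold (or 833) and tts-1 (3.76 ± 0.47) higher (camera adjusted p = 0.00995, or 0.103). Of 21 excitation genes 4 were higher (camera adjusted p = 0.00828, or 0.196).

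Ribosomal protein genes were lower in 76 of 78 cases in day 12 neurons (camera adjusted p = 4.74e-38, or 0.103 with an estimated correlation), with rpl-16 at -4.49 ± 0.29, and proteasome genes in 16 of 32, with pbs-4 at -3.72 ± 0.57 (28 over the list alone, camera adjusted p = 2.88e-11, or 0.0101). Genes of oxidative phosphorylation were lower in 17 of 40 cases, such as asg-1 (-3.53 ± 0.53) (camera adjusted p = 9.03e-08, or 0.172), citrate cycle genes in 8 of 26 (camera adjusted p = 0.000148, or 0.172). Chaperone genes were lower in 6 of 29 cases, with hsp-25 higher (5.98 ± 0.76, camera adjusted p = 0.00628, or 0.111). Germline genes were lower in 8 of 45 cases and cell cycle genes in 7 of 44 (camera adjusted p = 1.05e-07 and 3.24e-07, adjusted p = 0.103 and 0.172 with an estimated correlation). edgeR called 1085 genes (618 higher, 467 lower), 1077 with libraries that did not overlap (33.3% by chance). Under DESeq2's size factors the median of all genes moved from -0.62 to 0. Over the alternatives 36.1% (only the groups compared) to 82.7% (DESeq2's size factors) of calls were higher. The count was 559 or 487 without multiple-tissue replicate 1 or 2 and 535 or 505 without day 12 neuron replicate 1 or 2. Of 56 called genes looked at singly 31 kept their call each time, among them those given here with their log2 fold change, and 6 in no case.

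Between day 12 and young adult neurons edgeR called 2 genes, with 891 at an unadjusted p under 0.05. Thinned to 50000 reads, the day 12 libraries held 5079 and 5703 genes and the young adult ones 3176 and 3180. Transcripts of the neuropeptide gene nlp-20 went from 52360 ± 9881 CPM to 6484 ± 882, a log2 fold change of -3.01 ± 0.32 (SE, adjusted p = 0.0159), n = 2 per group. The chondroitin proteoglycan gene cpg-8 rose from 9.05 ± 2.54 (few reads: 3 counts are 5.43 CPM) to 254 ± 8.34 (4.80 ± 0.53, adjusted p = 0.0159). In both genes the libraries did not overlap (33.3% by chance). Neuropeptide genes lay lower as a list, with 1 lower and 0 higher of 50, and 3 and 0 adjusted over the list alone (camera adjusted p = 0.024, or 0.741 with an estimated correlation); their median log2 fold change was -0.48 and their mean 0.15. Not past the threshold, nlp-10 had -3.18 ± 0.64 (adjusted p = 0.126). Chaperone genes lay higher as a list of 29 (camera adjusted p = 0.00694, or 0.57), with 0 calls over all genes and 4 higher adjusted over the list alone; daf-21 had 2.95 ± 0.57 (adjusted p = 0.113) and hsp-1 4.58 ± 1.01 (0.126). Genes of oxidative phosphorylation (40, camera adjusted p = 0.000206, or 0.741) and ribosomal proteins (78, camera adjusted p = 0.00379, or 0.741) lay lower and innate immunity genes higher (18, camera adjusted p = 0.0318, or 0.741), each with 0 calls over all genes. DESeq2's Wald test called 315 genes, limma on log2(RPM + 1) 1087, limma voom with library weights 762, and edgeR with DESeq2's size factors 10, of which 9 were higher. Without young adult replicate 1 or either day 12 replicate 0 genes were called and without young adult replicate 2 there was 1. cpg-8 (4.54 to 5.11) and nlp-20 (-3.20 to -2.81) missed 0.05 without each of the 4 libraries in turn.

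Young adult muscle and neurons were compared with each other. Sarcomere genes were higher in muscle: mlc-2 was at least 3011-fold (or 1503) higher (16360 ± 421 CPM against 0), act-1 stood at 44390 ± 328 CPM against 208 ± 37.9, a log2 fold change of 7.74 ± 0.66 (SE, adjusted p = 0.000104), n = 2 per group, and unc-87 at 12.20 ± 0.81. Of 22 sarcomere genes 12 were higher in muscle and 1, the nonmuscle myosin light chain gene mlc-4 (-1.93 ± 0.51), lower (18 and 1 over the list alone, camera adjusted p = 1.22e-07, or 0.04 with an estimated correlation). Attachment genes were higher in 9 of 24 cases and lower in 1 (17 and 2 over the list alone, camera adjusted p = 0.000309, or 0.0295), with pfn-3 at 8.24 ± 0.88, dim-1 at 9.75 ± 1.15 and pxl-1 at least 39.6-fold (or 19.8) higher. With reads at cis sites counted as well, pxl-1 turned and was lower in muscle (-3.67, adjusted p = 0.00454, edgeR). The csq-1 and unc-120 genes were at least 86.7-fold (or 43.3) and at least 82.7-fold (or 41.3) higher in muscle. In neurons, 30 of 50 neuropeptide genes were higher and 0 lower, or 42 and 0 adjusted over the list alone (camera adjusted p = 2.41e-23, or 0.0271): nlp-10 was at least 14600-fold (or 4657) and flp-24 at least 5738-fold (or 1830) lower in muscle. Of 30 genes of the insulin and dauer list 7 were higher in neurons and 0 in muscle (camera adjusted p = 0.00159, or 0.04), with ins-17 at -9.09 ± 0.90. Pan-neuronal genes split: cpx-1 (-10.67 ± 0.86) and ptl-1 (-5.96 ± 1.25) were lower in muscle and unc-64 was at least 49.1-fold (or 24.5) higher in it (camera adjusted p = 0.0254, or 0.275).

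Ribosomal protein genes were higher in muscle than in neurons in 76 of 78 cases (77 over the list alone, camera adjusted p = 9.57e-35, or 0.0861 with an estimated correlation), with rpl-2 at 5.16 ± 0.34. Proteasome genes were higher in 16 of 32 cases, with pas-5 at 5.04 ± 0.56 (20 over the list alone, camera adjusted p = 4.36e-08, or 0.014). Chaperone genes were higher in 11 of 29 cases, with hsp-1 at 8.26 ± 1.10 (16 over the list alone, camera adjusted p = 9.12e-06, or 0.0295). Genes of oxidative phosphorylation were higher in 14 of 40 cases and lower in 1 (camera adjusted p = 0.00152, or 0.393), citrate cycle genes in 8 of 26 (camera adjusted p = 0.00252, or 0.275) and glycolysis genes in 6 of 26, with gpd-3 at 6.06 ± 0.66 (camera adjusted p = 0.00847, or 0.275). Of 8 operon downstream genes 3 were higher (camera adjusted p = 0.0308, or 0.34), including rla-1, an acidic ribosomal protein gene (7.82 ± 0.89). Of 18 innate immunity genes 2 were lower (camera adjusted p = 0.0206, or 0.34). edgeR called 1175 genes (776 higher in muscle, 399 lower), all with libraries that did not overlap (33.3% by chance). With DESeq2's size factors the median of all genes moved from 0.56 to 0. Over the alternatives 45.1% (DESeq2's size factors) to 78% (without young adult muscle replicate 2) of calls were higher in muscle. The count was 526 or 487 without muscle replicate 1 or 2 and 697 or 754 without neuron replicate 1 or 2, and 48 of 64 called genes looked at singly kept their call. ptl-1 (-7.40 to -5.18) missed 0.05 without young adult muscle replicate 1 or 2. mlc-4 (-2.02 to -1.83) lost the call without each of the 4 libraries in turn.

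Whether age changed muscle and neurons differently was tested by the interaction of age and tissue. It called 72 genes (edgeR; 18 with a more positive change in muscle and 54 with a more negative one; 1278 at an unadjusted p under 0.05). The actin gene act-1 had an interaction of -5.17 ± 0.74 (SE, adjusted p = 0.0225), with a change of -4.98 ± 0.58 in muscle and 0.19 ± 0.51 in neurons. Chaperone genes had a more negative change in muscle in 4 of 29 cases and in 17 adjusted over the list alone (camera adjusted p = 2.76e-10, or 0.00994 with an estimated correlation). Among them, daf-21 had an interaction of -6.24 ± 0.80, from -3.29 ± 0.56 in muscle and 2.95 ± 0.57 in neurons, and cct-5 of -4.74 ± 0.72. Proteasome genes had 0 single calls and 11 adjusted over the list alone (camera adjusted p = 3.78e-07, or 0.00994). Neuropeptide genes had a more positive change in muscle in 4 of 50 cases, nlp-20 (2.57 ± 0.42), flp-24 (11.34 ± 1.45), flp-26 and flp-28 (the flp genes had no read in young adult muscle, so their fitted values depend on edgeR's prior count), and in 17 adjusted over the list alone (camera adjusted p = 7.02e-16, or 0.0315). Sarcomere genes had a more negative change in muscle in 3 of 22 cases, act-1, mlc-2 and tni-1 (camera adjusted p = 0.00111, or 0.113), and ribosomal protein genes in 6 of 78, such as rpl-1 (-3.39 ± 0.51, camera adjusted p = 4.87e-07, or 0.594). The attachment (24, adjusted p = 0.0263) and glycolysis lists (26, adjusted p = 0.00142) lay lower and the insulin and dauer (30, adjusted p = 0.00301) and innate immunity lists (18, adjusted p = 0.0449) higher by camera. Each missed 0.05 with an estimated correlation (adjusted p = 0.113, 0.21, 0.0621 and 0.594 with an estimated correlation).

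The interaction changed with single libraries. It called 0 genes without young adult muscle replicate 1 or 2, without young adult neuron replicate 1 and without day 12 neuron replicate 1, 3 without young adult neuron replicate 2, 2 without day 12 neuron replicate 2, and 206 and 153 without day 12 muscle replicate 1 and 2. None of 24 called genes looked at singly kept its call throughout. flp-24 (11.10 to 11.89), flp-26 (8.84 to 9.68), flp-28 (8.03 to 9.38), nlp-20 (2.12 to 2.97), act-1 (-6.42 to -4.48), mlc-2 (-12.96 to -11.05), tni-1 (-8.93 to -6.12), rpl-1 (-3.71 to -3.05) and cct-5 (-5.32 to -4.31) missed 0.05 without young adult muscle replicate 1 or 2 or young adult neuron replicate 1 or 2 or day 12 neuron replicate 1 or 2. daf-21 (-6.84 to -5.04) lost the call without young adult muscle replicate 1 or 2 or young adult neuron replicate 1 or 2 or day 12 neuron replicate 1. With DESeq2's size factors 21 of 51 calls were more positive in muscle (41.2% in place of 25%), and the median of all genes moved from -0.93 to -0.70. The split turned in a fit of only the groups compared, where 51 of 71 calls were more positive in muscle (71.8%) and 38 of the 72 genes were called. With limma voom 14.7% were.

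**Figure D3:**
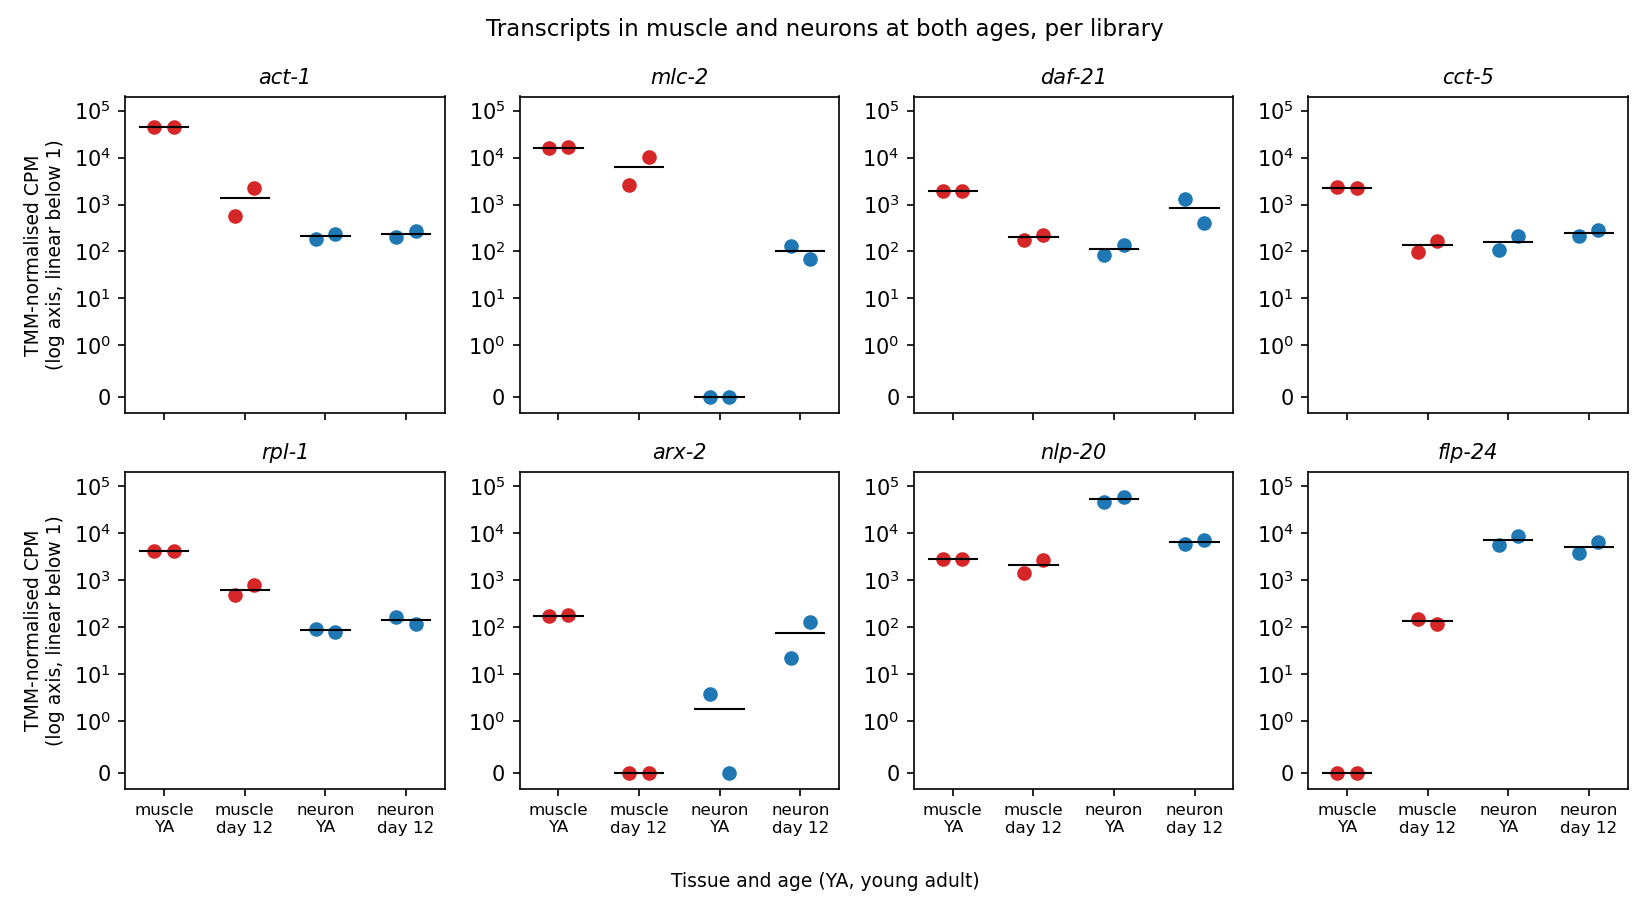
Normalised CPM of 8 genes in muscle (red) and neurons (blue) of young adults (YA) and on day 12, with 1 point per library and a line at the mean.

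The authors' deposited table of earlier gene sets names 5 sets of muscle genes, which were tested for overlap with the genes higher in each comparison by a one-sided Fisher's exact test over the 8954 tested genes. In the comparisons with multiple tissues, genes of muscle nuclei purified from young adults had the largest odds ratios: 156 of 562 were higher in young adult muscle (odds ratio 16, adjusted p = 6.23e-97), 156 in day 12 muscle (odds ratio 11.1), 170 in dauer muscle (12.1) and 132 in larval muscle (13.7). Of this set 100 genes were also higher in young adult neurons (odds ratio 2.82, adjusted p = 1.8e-15, Fisher's exact test) and 107 in day 12 neurons (odds ratio 3.63). In young adult muscle, genes bound by the muscle regulator HLH-1 (63 of 468; odds ratio 4.41), RNAs bound to tagged poly(A)-binding protein in L1 muscle (95 of 926; 3.46), genes of sorted embryonic muscle (270 of 4577; 3.28) and genes from reporter or immunostaining records (66 of 839; 2.34) overlapped less. In young adult muscle against neurons this order changed: the RNAs bound to poly(A)-binding protein (274 of 926; odds ratio 6.3) and the genes of sorted embryonic muscle (6.12) overlapped more than the purified nuclei (3.12). Of 35 tests 28 passed. With camera and an estimated correlation only the set of purified nuclei passed, in the 4 comparisons of muscle with multiple tissues (adjusted p = 0.0198, 0.025, 0.0201 and 0.0198 with an estimated correlation).

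The authors' deposited table of tissue markers lists 50 muscle genes, 35 of them tested. Of these, 15 were higher in young adult muscle than in multiple tissues and 0 lower (camera adjusted p = 3.5e-13, or 0.00247 with an estimated correlation), 13 and 1 in day 12 muscle, 12 and 0 in dauer, 14 and 1 in larvae, and 16 and 0 in young adult muscle against neurons. With age 2 fell in muscle and 0 rose (camera adjusted p = 6.92e-05, or 0.0165), in dauers 4 were lower than in larvae (camera adjusted p = 0.00222, or 0.0448), and in the interaction 3 had a more negative change in muscle (camera adjusted p = 0.00269, or 0.0448). In young adult neurons 3 were higher and 5 lower than in multiple tissues (camera adjusted p = 0.652). The deposited marker lists of germline (31 tested) and intestine (34) each had 1 gene lower and 0 higher in young adult muscle, and hypodermis (23) 0 and 0. How the authors chose these markers is not given in the sources used here, so their counts are not independent evidence.

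The authors' deposited tables also mark genes as enriched. Of 713 genes marked for young adult muscle 316 were called higher here, of 203 for day 12 muscle 176, of 588 for dauer 377, of 267 for larvae 167, of 870 for young adult neurons 596, and of 779 tested of 782 for day 12 neurons 485. None was called lower here (edgeR), and 8 of the larval genes had a log2 fold change below 0. For muscle age, the authors' deposited table marks 274 genes up and 149 down on day 12, of which 41 and 58 were called here in that direction. For neuron age the authors' deposited table marks 170 and 112, of which 1 and 1 were. The authors' deposited table of dauer against larvae marks 193 and 138, of which 118 were called higher and 22 lower here; 136 of the 138 were tested and 7 had a log2 fold change above 0.

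Reads at trans-splice acceptor sites showed whether muscle and neurons of young adults used different sites of the same gene. Of 161 genes with at least 2 tested sites (327 sites), 30 differed (edgeR's gene-level F test; 43 at an unadjusted p under 0.05). In zyx-1 (WBGene00006999), the zyxin gene on chromosome II, plus strand, 56.2% ± 4.3 (SD, n = 2) of muscle reads fell on the site at 13057095, exon 1 of an annotated transcript, and 0% of neuron reads (adjusted p = 0.00155). All neuron reads fell on the site at 13064886, exon 1 of a shorter transcript with 5 exons, which took 43.8% ± 4.3 in muscle. In aqp-7 (WBGene00000175), an aquaporin gene on chromosome X, plus strand, 55.1% ± 5.4 of neuron reads and 0.1% ± 0.1 of muscle reads fell on a site at 3025061 that lies upstream of the annotated exon 1, at 3025536 (adjusted p = 0.00155). In ZK512.2 (WBGene00013983; chromosome III, minus strand) muscle used the site at 9144794 for 96.5% ± 1.8 of reads and neurons that at 9143999 for 100% (adjusted p = 0.00189). In coq-3 (WBGene00000763; chromosome IV, minus strand), of ubiquinone synthesis, 87.1% ± 13.8 of muscle reads and 0% of neuron reads fell on 14796324. In K04B12.2 (WBGene00010550; chromosome II, minus strand) 83.4% ± 9.7 of neuron reads and 0% of muscle reads fell on 14436726. Positions are those of the deposited site table. The count was 8 without young adult muscle replicate 1, 8 without replicate 2, 18 and 34 without neuron replicate 1 and 2, 10 with sites of at least 50 reads and 50 with at least 3. With a block for replicate number 0 genes passed (edgeR, 34 at an unadjusted p under 0.05, smallest adjusted p = 0.0613). Of the 5 genes, zyx-1 and coq-3 could not be tested without either muscle library, aqp-7 and K04B12.2 without either neuron library, and ZK512.2 without any 1 of the 4, since fewer than 2 sites then held 10 reads in 2 libraries. In each other case they passed (adjusted p = 0.000762 to 0.0243).

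The L1, L2 and SL2-tag libraries have no replicate, so their unscaled CPM ratios carry no test. T05E7.4 stood at 245.4 CPM in L1 and 0.551 in L2 (174 reads and 1), a ratio of 446 (95% exact counting interval 78.9 to 17700), and wah-1, an apoptosis-inducing factor gene, was at least 413-fold higher in L1 (484 reads against 0). In L2, dao-2 (2392 reads against 0; at least 311-fold) and the saposin-like gene spp-5 (2047 reads against 0; at least 267-fold) were higher. Of 836 genes with at least 50 SL2-tag reads 771 lie in annotated operons (92.2%, against 13.5% of all genes in the table), and arl-5 (at least 950-fold), Y48E1C.4 (at least 538-fold), ZK20.4 (at least 511-fold), ndx-3 (at least 443-fold) and clk-1, a ubiquinone synthesis gene (429-fold), stood highest over the median of the 8 SL1-tag muscle libraries.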

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

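Of the tests in this part, those on sequencing depth as a source of the cis share, on both explanations for the dauer library, and on the spread between neuron replicates were chosen only after the result was seen.

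The change with age, which includes the drug given on day 12, differed between muscle and neurons in 72 genes by the interaction test in edgeR. The interaction was more positive in muscle for flp-24 (11.34 on the log2 scale), flp-26 (9.23), flp-28 (8.84), the long noncoding RNA tts-1 (3.86), the calmodulin-like gene cal-2 (3.49) and nlp-20 (2.57). It was more negative for dab-1 (-18.21), cdk-9 (-18.18), nkat-3 (-17.85), ent-1 (-17.47), arx-2 (-16.60), sgt-1 (-13.90), akir-1 (-12.78) and dnj-19 (-12.11). All of these genes except tts-1, cal-2 and nlp-20 had no read in at least 1 of the 4 groups, so their values depend on edgeR's prior count and are no bound. Each of the 72 is a difference between 2 tissues with 2 libraries per group.

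Reads at cis-splice acceptors are outside the gene counts, and their share lay above that of the multiple-tissue libraries (3.93% of site reads) in all other SL1-tag groups. It was 29.6% in L1 and 39.8% in L2 (1 library each), 13.7% in dauer, 14.3% in young adult muscle, 17.5% in day 12 muscle, 51.4% in young adult neurons and 53.4% in day 12 neurons. The antisense share was 5.50% in young adult and 4.64% in day 12 neurons. The SL2-tag library had 97.7% of its reads in operon genes.

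For the cis-acceptor share, priming on RNA of other cells alone would leave neuron genes unenriched among cis reads. The fixed neuron lists lay 2.98 above random matched genes in the log2 ratio of neuron over muscle (4.96 against 1.97). Random lists gave 1.09 to 3.18 (95%), and muscle lists differed by -4.41 (-2.49 against 1.92). A part from such priming stays open. A share, which depth is not expected to shift, cannot test shallow sequencing (3.75 times the multiple-tissue mean in the doubted dauer library). The level of tag expression, tied here to promoter and tissue, stays open, as does an untested difference between tissues.

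Dauer replicate 2 has the most reads and fewer genes than replicate 1. Depth is argued against: of 3405 genes at 10 to 100 CPM in replicate 1, 34.2% had no read in replicate 2 (95% Clopper-Pearson interval 32.6% to 35.8%). There 10 unscaled CPM are 95.9 reads. Of 204 genes above 1000 CPM 0 were absent, a ratio of at least 23.2 with 3 counts in place of 0. Few starting molecules before amplification stay open: absence that falls with abundance was also seen in day 12 muscle (45.9% to 0.52%), and other causes could give it too. A difference between the 2 dauer samples themselves stays open.

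edgeR called 2 genes for age in neurons and 139 in muscle. Lower depth stays open as a part. With muscle thinned to the neuron depths, muscle age fell to a median of 84.5 genes (SD 9.33 over 20 draws, 66 to 102). A wider spread between replicates cannot be judged, since the fit gave both comparisons 1 spread per gene. The coefficient of variation was 0.571 (young adult) and 0.411 (day 12) in neurons and 0.393 and 1.35 in muscle. The pattern depends on the test. With only the groups compared edgeR called 286 genes for neurons and 0 for muscle (625 and 1491 at an unadjusted p under 0.05), and with all groups limma on log2(RPM + 1) called 1087 and 881 and limma voom 762 and 660. The cause was not tested. A smaller change with age in neurons stays open and untested, and the interaction test covers single genes, not this difference in counts.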

How the results depend on the processing

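The settings with voom, with trans and cis sites and without the doubted libraries were chosen only after the result was seen.

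Counts of genes past the threshold depended on the processing, and the cause was not tested. As reported they are 458 (young adult muscle), 879 (day 12 muscle), 139 (muscle age), 667 (dauer), 628 (larvae), 295 (dauer against larvae), 1523 (young adult neurons), 1085 (day 12 neurons), 2 (neuron age), 1175 (muscle against neurons), 72 (the interaction), 105 (gene lists) and 30 (site use). Values more than 1.5 times away follow. DESeq2's Wald test gave 1201 (young adult muscle), 1722 (day 12 muscle), 882 (muscle age), 1408 (dauer), 1487 (larvae), 1168 (dauer against larvae), 1736 (day 12 neurons), 315 (neuron age), 1813 (muscle against neurons) and 543 (the interaction). DESeq2's size factors gave 10 (neuron age). No filter on low counts gave 1024 (young adult muscle), 1604 (day 12 muscle), 612 (muscle age), 1255 (dauer), 1372 (larvae), 666 (dauer against larvae), 2301 (young adult neurons), 1838 (day 12 neurons), 149 (neuron age) and 362 (the interaction). A filter of 50 counts in 2 libraries gave 258 (muscle age), 1033 (dauer), 994 (larvae), 582 (dauer against larvae), 18 (neuron age) and 136 (the interaction). Only the libraries of the groups compared gave 4417 (young adult muscle), 2777 (day 12 muscle), 0 (muscle age), 2150 (dauer), 5009 (larvae), 0 (dauer against larvae), 4195 (young adult neurons), 4023 (day 12 neurons), 286 (neuron age) and 2528 (muscle against neurons). The SL2-tag library as a further group gave 82 (muscle age), 9 (neuron age) and 46 (the interaction). limma on log2(RPM + 1) gave 1992 (young adult muscle), 2756 (day 12 muscle), 881 (muscle age), 2376 (dauer), 2448 (larvae), 1007 (dauer against larvae), 3770 (young adult neurons), 4226 (day 12 neurons), 1087 (neuron age), 2556 (muscle against neurons) and 1135 (the interaction). L1 and L2 as 1 group gave 93 (dauer against larvae). Camera with an estimated correlation gave 27 (gene lists). Sites with at least 50 reads gave 10 (site use). Sites with at least 3 reads gave 50 (site use). A block for replicate number gave 33 (neuron age), 113 (the interaction) and 0 (site use). limma voom with library weights gave 4636 (young adult muscle), 2480 (day 12 muscle), 660 (muscle age), 2013 (dauer), 4629 (larvae), 898 (dauer against larvae), 6495 (young adult neurons), 6130 (day 12 neurons), 762 (neuron age), 3941 (muscle against neurons) and 699 (the interaction). Counts over trans and cis sites gave 839 (young adult muscle), 1084 (dauer), 1258 (larvae), 457 (dauer against larvae), 2680 (young adult neurons), 2257 (day 12 neurons), 6 (neuron age) and 1906 (muscle against neurons). Without the doubted libraries there were 2868 (young adult muscle), 2205 (dauer), 3224 (larvae), 1724 (dauer against larvae), 4267 (young adult neurons), 3631 (day 12 neurons), 150 (neuron age) and 3244 (muscle against neurons).

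Leaving out 1 library at a time gave 175 to 204 (young adult muscle), 239 to 899 (day 12 muscle), 0 to 227 (muscle age), 229 to 1230 (dauer), 258 to 388 (larvae), 48 to 524 (dauer against larvae), 745 to 918 (young adult neurons), 487 to 559 (day 12 neurons), 0 to 1 (neuron age), 487 to 754 (muscle against neurons), 0 to 206 (the interaction) and 8 to 34 (site use). The counts of 0 come from edgeR, in muscle age, neuron age and the interaction, where 1724, 891 and 1278 genes have an unadjusted p under 0.05 as reported and DESeq2's Wald test gave 882, 315 and 543. With only the groups compared 1491 (muscle age) and 1442 (dauer against larvae) had one in edgeR, as had 34 in site use with the block. Replicate numbers showed no pairing (0 of 15 pairs of groups had a correlation above 0.1, range -0.037 to 0.017).

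For the genes looked at singly, 6110 combinations of gene and alternative kept direction and side of the threshold, 907 no longer passed, 64 newly passed and 2 turned. The 2 are myo-3 in day 12 muscle without day 12 muscle replicate 2 (-2.11, adjusted p = 0.806, edgeR, with 7.28 the highest of its leave-outs) and pxl-1 in muscle against neurons with trans and cis sites (-3.67, adjusted p = 0.00454, edgeR). Of all called genes more turned, at most 19 (young adult neurons) and 17 (muscle against neurons) with trans and cis sites and 8 (day 12 neurons) without day 12 neuron replicate 2. For lists, 319 kept their call and 101 did not. The doubted libraries could not be left out of the comparisons with day 12 muscle, since none would remain, so these were not run. Depth limits neuron libraries most (3 counts: 52.5 unscaled CPM in the shallowest).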

Other observations

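No hypothesis beyond the weighed patterns was tested, and no test in this part was chosen after the result was seen. The SL2-tag library held 2520944 gene reads on 992 genes, with 2.39% of its site reads at cis-splice acceptors.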
